A study of Homo sapiens with 3 samples.

How the data were processed

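Gene-level FPKM for 3 libraries of 786-O cells were used as the authors deposited them. Reads were handled with CASAVA 1.8, TopHat2 2.0, Bowtie 0.12.7 and Cufflinks 1.3 on hg19, per the submitters' processing notes. The gene annotation, strandedness and read numbers were not given in the sources used here. Per the file headers, each row gave an FPKM, a lower and an upper confidence bound and a status. Each table held 24788 rows and 23146 symbols, the same in all 3 libraries.

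The status was LOWDATA for 275 rows in each library, and FAIL for 11 rows in the parental, 25 in the shRNA and 31 in the CRISPR library. The 320 rows not OK in at least 1 library were left out, and rows of a symbol were summed (534 symbols had more than 1 row), leaving 22957 symbols. Genes with a mean FPKM of at least 1 were kept, 11995 in all. Values were analysed as log2(FPKM + 1), so log2 ratios understate the change of low genes. Coordinates are those of the deposited tables (hg19), counted from 1.

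Fragments behind each value were estimated from the confidence bounds, assuming that the half-width is 2 counting standard deviations. Among rows implying 0.5 to 30 fragments, 54.2% to 57.6% came out whole within 0.01, so the values were not treated as counts. The bounds of each value come from 1 library, so they hold no variation between cultures. Whether they cover counting error only was not established.

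Groups came from the labels: 1 high-HIF library and 2 low-HIF libraries. They were compared with limma 3.58.1 (trend) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The fit had 1 residual degree of freedom and 4.33 prior degrees of freedom, and the lone parental library was assumed to vary like the low-HIF ones. A permutation of 1 library against 2 cannot give a p below 0.333. Comparisons of single libraries used a size rule of at least 1 log2 unit, with no p-value. Nothing in the labels said whether the low-HIF libraries came from separate cultures.

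For 28 gene lists fixed before the data were examined, the median log2 ratio was placed among 10000 random lists of equal size matched on expression in 20 bins (2000 for the alternative settings), as a description, with the outer 2.5% on either side as bounds. Fry tested the lists, with adjustment over them. The genes named were ARNT and EZH1, the 12 largest changes each way in both ARNT-targeted libraries at a mean FPKM of at least 5, up to 4 members per list with the largest change, members of the demethylase, PRC2 and bHLH-PAS lists, and the 5 largest each way in each ARNT-targeted library alone. Exceptions are marked in the text, and some genes that the rule selects are not reported here.

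On simulated libraries of 11995 genes with 200 changed, limma recovered 8% of genes changed by 1 log2 unit, 80% at 2, 90% at 3 and 98% at 4 in the low-HIF versus high-HIF comparison, and the size rule 34%, 96%, 100% and 100%. Of the unchanged genes, limma called 11 (0.093%) and the size rule 1.31%. The simulated noise was equal for all genes of an expression bin, so these rates do not carry over to the real fit. There CRYAB, with a mean log2 difference of 4.34, was not called.

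Alternatives covered the pseudocount (0.1 and 5), the filter (none and 5), 3 rescalings, duplicate symbols, row status, leaving out each low-HIF library, the variance model, non-overlap of bounds and fry without trend. Added after seeing the data were leaving out small RNA symbols and removing trends with transcript length and GC content. Length and GC came from GENCODE 29 by symbol for 10565 genes (88.1% of those kept), and no coordinates were taken from it. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used.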

Results

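The series measured the transcriptome of 786-O cells, an established clear cell renal carcinoma line that lacks functional VHL and so keeps hypoxia-inducible factor (HIF) active in normal oxygen. It held 3 RNA-seq libraries. The parental library made up the high-HIF group (n = 1). The low-HIF group (n = 2) held a library with an shRNA against ARNT, the subunit that HIF-1 and HIF-2 need to bind DNA, and a library labelled as lenti-CRISPR editing of ARNT. The series title asks how HIF-responsive histone demethylases relate to the dependence of VHL-null cells on EZH1, a catalytic subunit of Polycomb repressive complex 2 (PRC2). Depth, read back from the deposited confidence bounds, was estimated at 5372254 fragments for the parental library, 13608869 for the shRNA library and 14538211 for the CRISPR library. The median half-width of those bounds at an FPKM of at least 1 was 18.4%, 9.92% and 10.1% of the value. Because the parental library was single, no difference from it has a replicate check of its own. The p-values below rest on the spread between 2 libraries that differ in how ARNT was targeted. In the main fit that spread came in larger part from all genes (4.33 prior degrees of freedom) than from each gene itself (1 residual).

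ARNT, at chromosome 1, 150782181 to 150849244 (hg19), stood at 4.97 FPKM in the parental library, 2.04 in the shRNA library and 9.45 in the library labelled CRISPR. Relative to the median of all genes, its log2 ratio to parental was -1.40 with the shRNA and 0.40 with CRISPR. The transcript was thus lower only in the shRNA library. An edit of the coding sequence need not lower the transcript, so this level does not check the CRISPR label. Among the other factors of the bHLH-PAS family, EPAS1, which encodes HIF-2α, was higher in both ARNT-targeted libraries, at 6.55, 33.3 and 16.8 FPKM in the parental, shRNA and CRISPR libraries. HIF1A stood at 5.53, 7.86 and 16.3 FPKM. The median of the 8 measured members lay at percentile 96.1 of random lists matched on expression, or 68.8 with length and GC trends removed. No member passed the limma test in the main setting, though EPAS1 did under another.

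HIF-2-linked targets of renal carcinoma were low relative to other genes in the ARNT-targeted libraries. The median of the 15 measured members, relative to all genes, was -1.11 with the shRNA and -0.53 with CRISPR, at percentiles 0.11 and 1.37 of random lists. Of the 15, 10 lay below the median of all genes in both libraries and 2 above it in both. On the deposited scale the list medians were -0.69 with the shRNA and -0.11 with CRISPR. On that scale 7 members were below 0 in both libraries, 5 above 0 in both and 3 of opposite sign. By the size rule 2 were lower and 1 higher in both on the deposited scale, and 3 and 1 relative to the median of all genes. CCND1, the cyclin D1 gene, stood at 140.7 FPKM in parental cells, 10.7 with the shRNA and 39.0 with CRISPR (limma adjusted p = 0.134). EGLN3, a HIF prolyl hydroxylase, stood at 11.5, 0.961 and 6.85 FPKM (adjusted p = 0.228), and EDN1, the endothelin-1 gene, at 3.31, 0.754 and 1.11 FPKM (adjusted p = 0.134). IGFBP3 went the other way, at 119.4, 325.7 and 378.9 FPKM. By limma in the main setting, no member of the list was called, either over all genes or adjusted over the list alone. Under some other settings CCND1, EGLN3, IGFBP3 and EDN1 were called. Fry, which asks whether the members move one way on balance without comparing them with other genes, gave an adjusted p of 0.842. The list median stayed below percentile 2.5 under every setting tried.

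The wider list of canonical HIF targets did not stand apart, with its 29 measured members at percentile 39.7, but this position moved with the filter. It was 3.90 with a filter of 5 (21 members) and 2.80 without a filter (35 members), both just inside the lower bound. Of these, 4 were higher and 0 lower by at least 1 log2 unit in both libraries on the deposited scale, and 2 and 2 relative to the median of all genes. MXI1 was among the higher ones at 0.773, 6.95 and 5.05 FPKM, as was PFKFB3, a regulator of glycolytic flux, at 11.3, 60.8 and 34.8 FPKM. Between the ARNT-targeted libraries 16 of the 29 were higher with CRISPR and 13 with the shRNA. In some of the 29, EGLN3 (given above) among them, the shRNA library was lower than both others. Another 3 such members were chosen after their values were seen. NDRG1 stood at 42.0, 7.56 and 36.7 FPKM, SLC2A1 at 55.0, 19.6 and 70.0, and VEGFA at 23.7, 11.3 and 21.7. SLC2A1 and VEGFA also belong to the HIF-2-linked list, which shares members with this one. The glycolysis list lay at percentile 0.98 with the shRNA and 7.58 with CRISPR. Over both libraries it lay at 2.89, inside the bounds, and at 20.05 after quantile normalization, 9.1 with length and GC trends removed and 1.10 without a filter. Of its 18 members, 14 lay below the median of all genes in both libraries and 3 above it in both. Its member ENO2 stood at 17.9, 7.78 and 10.6 FPKM. The 3 above were PFKM (13.0, 30.9 and 23.9), PGAM1 (369.4, 652.6 and 710.3) and PGK1 (120.5, 234.0 and 209.7). By the size rule, 0 of 18 members were apart in both libraries on the deposited scale.

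**Figure D1:**
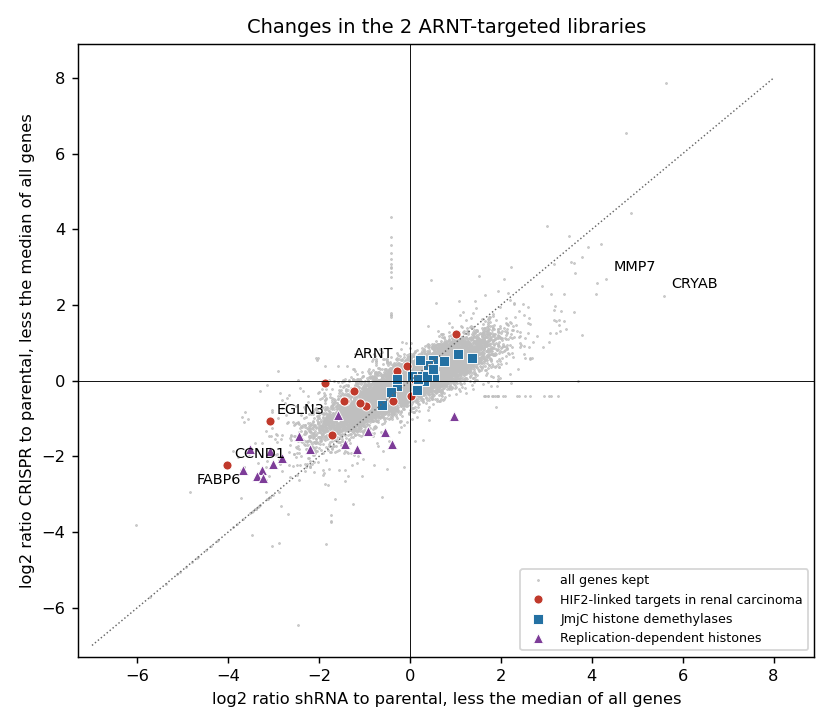
Each point is a gene; the axes give its log2 ratio of shRNA (x) and CRISPR (y) to the parental library, less the median of all genes, with the dotted line marking equal change. HIF-2-linked targets (circles) and histones (triangles) lie mostly at the lower left, and CCND1 sits at -4.02 and -2.24; JmjC demethylases (squares) lie around 0.

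Histone demethylases of the JmjC family, several of them described as HIF-responsive, were not low as a list in the ARNT-targeted libraries. Their median lay at percentile 76.5, and of the 18 measured members 2 were higher and 0 lower by at least 1 log2 unit in both libraries on the deposited scale. Relative to the median of all genes, 0 were higher and 0 lower by that much in both. KDM5B, an H3K4 demethylase, stood at 3.36, 14.1 and 7.82 FPKM, and KDM4A at 5.41, 16.8 and 13.0 FPKM. KDM6A, an H3K27 demethylase, stood at 0.637, 2.71 and 2.10 FPKM. KDM3A, a known HIF target, was at 2.77, 5.30 and 3.95 FPKM, and KDM4B at 5.35, 5.37 and 5.91 FPKM. Relative to all genes, the signs of KDM3A and KDM4B were not the same under every setting. The LSD1-family members KDM1A and KDM1B were both above the median of all genes in both libraries (percentile 84.0). None of the JmjC genes passed limma over all genes, and 0 passed adjusted over the list alone.

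EZH1, at chromosome 17, 40852293 to 40897071, stood at 1.81 FPKM in parental cells, 3.06 with the shRNA and 3.34 with CRISPR. Its log2 difference between low and high HIF was 0.58 with a standard error of 0.32, which did not pass limma (adjusted p = 0.261). Relative to the median of all genes it was 0.16, a value that limma did not test. EZH2, the other PRC2 methyltransferase, stood at 16.0, 14.9 and 27.0 FPKM. The median of the 11 PRC2 genes lay at percentile 66.0. EED stood at 1.88, 5.30 and 7.49 FPKM, and JARID2 at 3.59, 2.57 and 2.82 FPKM. Among chromatin lists, PRC1 (percentile 53.3), SWI/SNF (43.4) and the DNA methylation enzymes (39.0) lay well inside the random range. Fry called 2 lists upward, PRC1 (adjusted p = 0.0118) and other 2-oxoglutarate oxygenases (adjusted p = 0.0480, percentile 85.9). Both calls were lost after median ratio scaling, and with each library rescaled to an equal sum the only list called was PRC2 (adjusted p = 0.0246), also upward. In the oxygenase list, PLOD2, a collagen lysyl hydroxylase, stood at 17.1, 106.8 and 65.9 FPKM.

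**Figure D2:**
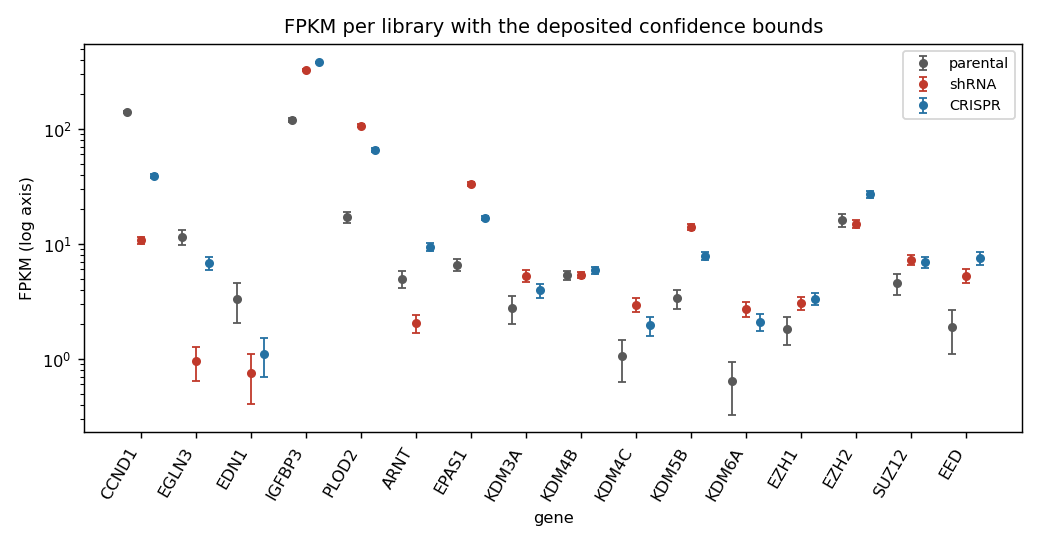
FPKM (log axis) of genes in the HIF, bHLH-PAS, demethylase and PRC2 lists in the parental, shRNA and CRISPR libraries, 1 library each, with the deposited confidence bounds as bars. CCND1 is highest in the parental library at 140.7, while EZH1 lies between 1.81 and 3.34 in the 3 libraries.

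Across all 11995 genes kept, 1451 were higher and 271 lower by at least 1 log2 unit in both ARNT-targeted libraries. That balance came with a shift of the whole distribution, since the median log2 ratio of all genes was 0.42 with the shRNA and 0.41 with CRISPR. After median ratio scaling the counts turned to 361 higher and 834 lower. As background, 301 genes were higher and 184 lower in the shRNA library alone, and 37 and 26 in the CRISPR library alone. These counts moved with the setting. For the shRNA they were 87 and 46 with pseudocount 5, and 594 and 218 with libraries rescaled to an equal sum. For CRISPR they were 12 and 7 without small RNA symbols, and 80 and 27 without a filter. The largest higher genes included CRYAB, a small heat shock protein (1.96, 190.8 and 17.8 FPKM), the matrix protease MMP7 (0.20, 31.2 and 9.37), the claudin CLDN2 (1.15, 49.2 and 16.2) and the complement regulator CFI (1.77, 62.4 and 16.9). They also included the cadherin CDH6 (10.1, 144.5 and 43.8), carbonic anhydrase CA2 (10.8, 141.0 and 55.7) and ALDH1A1 (29.1, 436.9 and 102.3). AKR1C3, MAL2, GDF15 and L1CAM completed this group, with TMEM183A, a gene with a close paralog and therefore uncertain, which was near 0 in the parental library. The largest lower genes were FABP6, a bile acid binding protein (32.6, 0.565 and 4.85 FPKM), VTRNA1-1, CCND1, INHBA, an activin subunit (36.3, 2.87 and 8.49), and 8 histone genes. HIST2H3A and HIST2H3C had identical values and cannot be separated.

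With limma, 8 genes were higher and 24 lower at an adjusted p under 0.05, and all 32 were small RNAs, listed at or near 0 in either the parental library or both others. No other gene was called. The limma fit used the deposited scale, where the median log2 ratio of all genes over both libraries was 0.43. The balance of higher and lower genes in it therefore carries that shift, and does not show the direction of the change. Among the 24 largest genes above, adjusted p ran from 0.0674 for TMEM183A to 0.151 for L1CAM. Leaving out small RNA symbols, a choice made after seeing the data, gave 766 higher and 91 lower, and robust empirical Bayes gave 99 and 59.

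**Figure D3:**
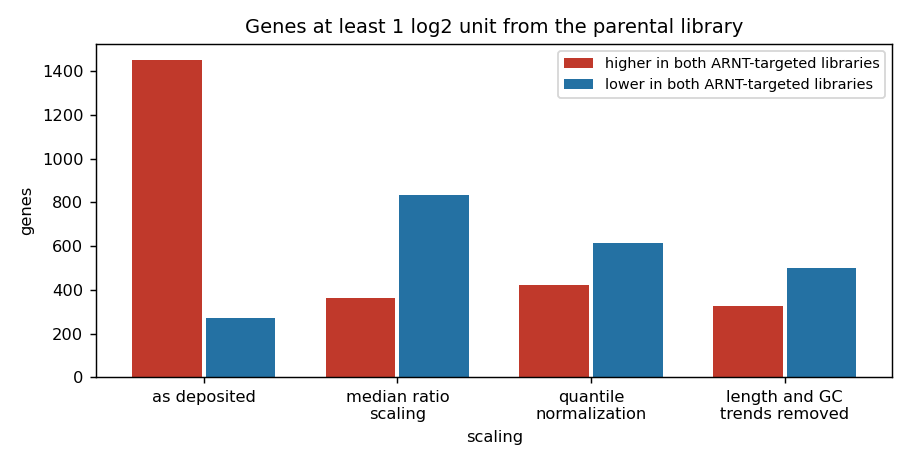
Number of genes at least 1 log2 unit higher or lower than the parental library in both ARNT-targeted libraries, as deposited and under 3 other scalings. As deposited 1451 were higher and 271 lower, and after median ratio scaling 361 were higher and 834 lower.

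Replication-dependent histones were the lowest list, at percentile 0 in both libraries, with 11 of 17 measured members lower by at least 1 log2 unit in both and 11 called adjusted over the list alone, though 0 over all genes. Fry did not call the list (adjusted p = 0.248). HIST1H4C stood at 22.1, 1.41 and 4.95 FPKM. Small structural RNAs were also low (percentile 0, 3 of 5 lower), with RMRP at 862.7, 217.5 and 288.2 FPKM, but the list lay at percentile 20.6 once length and GC trends were removed. As deposited, cytosolic ribosomal protein genes lay at percentile 1.09, and at 13.7 after quantile normalization. Small RNA symbols took 2.32% of the FPKM sum in the parental library and 1.44% and 1.40% in the others. The parental library thus also differed in its measured share of small RNAs. Whether the RNA or the library preparation differed, and whether that bears on the low histones and small RNAs, was not tested.

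Each ARNT-targeted library was also set against the parental one. With the shRNA, 3036 genes were higher and 884 lower by at least 1 log2 unit, and with CRISPR 1684 and 315. The log2 ratios correlated across genes (Pearson r = 0.84, covariance 0.55, same sign in 86.4%), although genes are not independent replicates. Simulated libraries without effect that shared a single control gave r = 0.50 and a covariance of 0.14, a difference in covariance of 0.42. In these a mean of 72 genes were higher and 73.9 lower in both. With the counting noise of the parental library added, they gave r = 0.53, a covariance of 0.157 (difference 0.398) and 98.9 higher and 98.6 lower genes. Lists drawn independently with the observed sizes would share 426.2 higher and 23.2 lower. The simulations have no shift of all genes and take the noise from the spread between the ARNT-targeted libraries, so a larger deviation of the single parental library is not covered.

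The ARNT-targeted libraries differed from each other in 293 genes higher and 339 lower with CRISPR. Cell proliferation genes were lower with the shRNA than with CRISPR in all 23 measured members. Their median lay at percentile 0.39 with the shRNA and 72.0 with CRISPR, and 8 members lay below the median of all genes in both libraries. Over both libraries the list lay at percentile 8.96, and at 1.60 once length and GC trends were removed. MCM5, a replication helicase subunit, stood at 64.6, 19.9 and 51.8 FPKM and the mitotic gene CDC20 at 185.4, 68.9 and 179.3. Targets of p53 were higher with the shRNA (percentile 100) than with CRISPR (80.9), and lay at 99.5 over both, above the upper bound in every setting that kept both libraries. They were led by GDF15 at 1.87, 33.9 and 14.1 FPKM. Interferon-stimulated genes lay at percentiles 97.7 and 72.2, and over both inside the bounds. Genes highest in the shRNA library alone included RGS5, listed at 0 in parental cells, and genes lowest there included SLC38A5 and C1QL1. CRISPR alone was highest for TNC, CCNA2, SEMA4B, CLDN1 and WLS, and lowest for VTRNA2-1, HIST1H2AC, RPL21 and RPL17-C18ORF32. The last pair may share reads with related sequences, which was not tested, and is uncertain.

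Of the remaining lists, extracellular matrix and mesenchymal genes lay at percentile 98.1, but inside the bounds after median ratio scaling (96.8) and with the shRNA library alone (93.8), with FN1, the fibronectin gene, at 197.4, 747.3 and 405.8 FPKM and COL6A2 lower at 140.6, 40.5 and 76.2. NF-kB and cytokine genes lay at percentile 3.06, and at 2.30 after quantile normalization. Cholesterol synthesis (82.5), AHR targets (86.2), the unfolded protein response (50.6), the respiratory chain (58.9), serine and one-carbon genes (24.9), immediate-early genes (32.6) and tubule genes (57.1) lay inside the random range. Of the leukocyte markers only LYZ passed the filter (33.1, 10.4 and 12.3 FPKM), and no endothelial marker did.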

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

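Tests here were chosen after the results were seen, except that of the genes around ARNT. Differences between the shRNA and CRISPR libraries below are opposite signs against the parental library. They rest on 1 library each and were not tested.

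The ARNT transcript was lower than parental with the shRNA and higher with CRISPR, a difference of 1.78 on the log2 scale (CRISPR minus shRNA). The CRISPR ratio less the median of all genes was at least 0.29 under the 4 scalings. A scaling moves all genes nearly alike, so this does not test the scale of the values as a cause, which stays open. A gain of the region is argued against, since 60 genes within 2 Mb had a median of -0.14 with a standard error of 0.16. The ratio is not unusual among genes, at percentile 76.3, so variation between single libraries stays open. So do a response to the edit and a wrong label, neither of which was tested.

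Opposite signs were also seen for the medians of cell proliferation genes (difference 0.82) and of NF-kB and cytokine genes (0.39). Single genes were EZH2 (0.81), SLC38A5 (3.02), C1QL1 (3.03), TNC (1.50), CCNA2 (1.35), SEMA4B (1.37), RPL17-C18ORF32 (-1.73), RPL21 (-1.32) and HIST1H2AC (-1.28). The genes named for being apart in 1 library were picked for that difference. These signs are on the deposited scale. Relative to the median of all genes, the NF-kB list was low in both libraries (-0.70 and -0.38), and SLC38A5, C1QL1, RPL21 and HIST1H2AC also had the same sign in both.

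Among rows left out for their status, ASPH, an aspartyl hydroxylase, was listed at 0 in the parental library, where its estimate had failed, and at 243.9 and 145.8 FPKM in the shRNA and CRISPR libraries (mean 194.8). NCRNA00188 was likewise listed at 0, 365.8 and 309.5 FPKM (mean 337.7). A failed estimate at 0 is not a measured absence.

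Most genes apart from the parental library were higher in both ARNT-targeted libraries, 84.3% as deposited. After median ratio scaling the share was 30.2%. That scaling brings the median of all genes to about 0 by construction, so it does not test the cause, and the direction of the balance stays open. That many genes stood apart at all is a separate matter. Low parental depth as the whole cause is argued against. Of the 1705 such genes on 1 row as deposited, 92.4% had bounds that did not overlap the parental ones. The share was 97.3% for the 1441 higher and 65.9% for the 264 lower genes, so depth stays open for part of the lower ones. GC content and length stay open in part, on another set of genes. Of 1039 genes apart after median ratio scaling, 57.8% (601) were still apart in the same direction once both trends were removed. After that scaling more genes were lower than higher. HIF state and the parental library cannot be told apart, because that library was the only one of its group.

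The CRISPR library lay nearer to the parental one than the shRNA library did. With length and GC trends removed, 83.2% of genes apart in both had the smaller change with CRISPR, which argues against those trends as the cause. A mixture of parental-like and edited cells stays open. The first test compared the shRNA-like fraction of lower and higher genes among those apart in both libraries and gave a difference of 0.23. A second, choosing genes by the shRNA library alone, was added after that value was seen and gave 0.35. The second is void, because simulated mixtures themselves gave 0.105 there, above the limit of 0.1 set for the test. In the first they gave 0.07, less than the 0.23 found, but the simulation assumed a single fraction (0.6) and noise level, so a mixture is not excluded. Weaker loss of ARNT function in all cells was not tested.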

How the results depend on the processing

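Settings that remove small RNAs or trends with transcript length and GC content were chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Leaving out a low-HIF library leaves no residual degrees of freedom, so limma was not run there. The position of HIF-2-linked targets (percentile at most 1.37) and of histones (0) held in every setting, and r stayed between 0.82 and 0.88. Ribosomal protein genes lay between percentiles 0 and 13.7. Of 155 named genes, 131 kept their sign relative to all genes and 24 did not under the settings that kept all libraries, among them KDM3A, KDM4B, EZH2 and SUZ12. Some settings test fewer genes, and unless stated the cause of the moves below was not tested. The prior degrees of freedom of limma also moved, from 4.33 in the main fit to 0.84 without a filter. They were 10.7 without small RNA symbols, 33.7 with the length trend removed and 8.12 with robust empirical Bayes.

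Pseudocount 0.1 gave 2328 genes higher in both libraries, 2675 higher with CRISPR, 480 higher and 555 lower with CRISPR than with the shRNA, 25 and 15 limma calls, -1.74 for ARNT with the shRNA, 1 list above the upper percentile bound and 1 fry call, PRC1. Pseudocount 5 gave 386 higher and 118 lower in both, 1274 and 454 with the shRNA, 460 and 144 with CRISPR, 85 and 94 between the ARNT-targeted libraries, 1 limma call upward and -0.75 for ARNT.

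Median ratio scaling gave 361 higher and 834 lower in both, 1455 and 1844 with the shRNA, 425 and 900 with CRISPR, 1 list above the upper percentile bound and 0 fry calls. Quantile normalization gave 422 and 616 in both, 1568 and 1575 with the shRNA, 501 and 679 with CRISPR, 14 limma calls upward and 0 fry calls. Rescaling each library to an equal sum gave 658 lower with CRISPR than with the shRNA, 12 limma calls downward, 1 list above the upper percentile bound and 1 fry call, PRC2, which was not called as deposited. Under median ratio scaling and equal sums the list no longer above the bound was the extracellular matrix list, as with pseudocount 0.1 and without a filter. The limma split was 8 higher to 24 lower as deposited, 8 to 32 with median ratio scaling, 14 to 35 with quantile normalization and 8 to 12 rescaled to an equal sum.

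Removing the length trend gave 350 and 577 in both, 1259 and 1497 with the shRNA, 408 and 663 with CRISPR, 404 and 616 limma calls and 0 fry calls. Removing length and GC trends gave 326 and 499 in both, 1056 higher with the shRNA, 377 and 576 with CRISPR, 12 limma calls downward and 0 fry calls. Without small RNA symbols there were 164 lower in both, 192 lower with CRISPR, 766 and 91 limma calls and 0 fry calls.

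A filter of 5 gave 150 lower in both, 172 lower with CRISPR, 190 and 197 between the ARNT-targeted libraries, 24 limma calls upward and 0 fry calls. Without a filter there were 0 limma calls either way, -0.97 and 0.78 for ARNT with the shRNA and CRISPR, 1 list above the upper percentile bound and 0 fry calls. Without the filter the median log2 ratio of all genes over both libraries was 0.03, against 0.43 with it. Values relative to that median therefore rose, as for ARNT above and for KDM4B, from -0.36 to 0.04. Requiring bounds that do not overlap, which was possible only for the 11845 genes on 1 row, gave 174 lower in both, against 264 on those genes without it. Robust empirical Bayes gave 99 and 59 limma calls, and no trend gave 14 downward. Fry called 0 lists without symbols on several rows, 0 without trend and 1, PRC1, with all rows kept. Leaving out a low-HIF library gave 1 to 2 lists above the upper bound and 5 to 8 below the lower bound, against 2 and 5 with both.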

Other observations

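Tests in this part were chosen after the results were seen. The lists were written after the largest changes had been seen, CFI and AKR1C3 among them, and 3 lists were tried.

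The median of complement components and regulators was high in both ARNT-targeted libraries, although not every member was. Without CFI, which prompted the list, the median of 9 genes lay at percentile 98.8 or above in both libraries with length and GC trends removed. With CRISPR that median (0.47) was the value of a single low gene, CFD, at 1.02, 0.478 and 1.83 FPKM. CFD was below 0 with the shRNA (-0.12), so the CRISPR position rests in part on a gene near the filter. Of the 9, 7 were above 0 with the shRNA and 5 with CRISPR. C3 was 2.36 higher with the shRNA and 1.22 higher with CRISPR on the log2 scale after that removal. CD46 stood at 8.40 FPKM in parental cells, 49.8 with the shRNA and 26.4 with CRISPR. C1S was higher with the shRNA (1.35, 8.62 and 1.95 FPKM), and with CRISPR it was below 0 after the trends were removed, as were CFB, CD59 and CD55. This is a hypothesis found and tested on the same libraries, and it may reflect any difference between the parental library and the others.

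NRF2 targets were tested because AKR1C3 was among the largest changes. Without it, the median of 14 genes lay at percentile 94.5 with the shRNA and 72.8 with CRISPR, inside the random range. SRXN1 stood at 2.96, 12.8 and 13.1 FPKM, and NQO1 at 53.5, 62.8 and 62.7.

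MHC class I presentation genes were tested after the interferon-stimulated list had been seen. The median of 14 genes lay at percentile 97.8 with the shRNA and 72.6 with CRISPR, so the libraries did not give one answer. B2M stood at 302.8, 765.2 and 520.0 FPKM.

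The log2 ratios followed GC content across 10565 genes. Spearman's rho was -0.38 for the shRNA and -0.23 for CRISPR against parental, and 0.44 for CRISPR against the shRNA. Genes of chromosome 19 had a median of -0.61 with the shRNA and -0.35 with CRISPR relative to all genes.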
